A study of Mus musculus with 60 samples.

How the data were processed

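RNA was sequenced from the tibias of female C57BL/6N mice aged 5 or 22 months. Per the labels' protocols, the right tibia was loaded in axial compression and the left tibia of the same mouse was the contralateral non-loaded control. Loading ran at 4 Hz for 1200 cycles per day, with a rest of 0.1 s, a preload of -0.5 N and a peak force of -8 N or -7 N set by age to reach a peak strain of -2200 microstrain. Tibias were taken after 1, 3 or 5 days of loading. Per the same protocols, the bone was trimmed 2 mm below the plateau, muscle was stripped, marrow was removed by centrifugation, 1 µg of RNA entered a ribosomal RNA depletion, and single reads of 50 bases were sequenced. The labels give RNA integrity numbers with a median of 7.5 (6.6 to 8.7).

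Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, aligned with STAR 2.0.4b to GRCm38 and counted per gene with Subread featureCounts 1.45. The version of the gene annotation is not stated. Each deposited file holds 1 library with 3 values per gene: the count, which the authors did not normalise, the CPM, which the authors scaled to the total count of the same library, and the RPKM, which the authors obtained from the CPM and the gene length. Both relations were checked on the files. Only the counts were used here. Of 41388 genes in the files, 40254 had a symbol, and these held 99.86% of the counts.

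There were 60 libraries from 30 mice, 5 mice for each of 6 combinations of age and day, and 12 groups of 5 libraries. Mice 1 to 5, 6 to 10 and 11 to 15 were the 5-month mice of days 1, 3 and 5, and mice 16 to 20, 21 to 25 and 26 to 30 the 22-month mice of the same days. The title and the loading status field of the labels disagreed for 30 libraries, all of days 3 and 5. Groups were taken from the titles, because the field would give groups of 4 and 6 on day 3. A list of 12 load-induced genes, fixed from background knowledge, served as a check of that choice. It is also reported among the gene lists, where its direction on days 3 and 5 is no separate evidence of a loading response. Total counts ranged from 7.27 to 27.84 M (M, mega) per library. Counting error only is covered by any statement about depth, since the reads carried no molecular identifiers.

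Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 18543 genes over all libraries and 17967 over the 30 non-loaded ones. Library sizes were scaled by TMM. Loading was tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood F tests in 1 fit over 60 libraries with 30 mouse terms, so that each mouse was its own block, and 6 loading terms (24 residual degrees of freedom). Contrasts of that fit gave loading in each age and day, the age-by-loading difference (22 minus 5 months) on each day and averaged over days, and the difference of loading between days within each age (2 degrees of freedom). A separate fit over the 30 non-loaded libraries gave age (22 minus 5 months, averaged over days) and differences between days within an age. P values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. The standard error of a log2 change was its size divided by the square root of F. CPM values in the text were computed on TMM-scaled libraries, and log2 CPM used a prior count of 2.

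Fixed before the data were examined were 32 gene lists (bone cells, matrix, signalling pathways, metabolism, and markers of other cell types that bone can carry). Of their symbols, 2 were not matched. Lists of at least 5 tested genes were tested against all other genes with camera of limma 3.58.1, with a preset inter-gene correlation of 0.01 and, as an alternative, an estimated one. List p values were adjusted over the 32 lists of a comparison. Of 176 list calls, 6 held with an estimated correlation. Most camera calls therefore rest on the preset correlation and do not by themselves show that a list moved against the other genes. Beside the count of members past the threshold over all genes, the count adjusted over the list alone is given.

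The genes named were chosen by a rule set at the same time. They are the 10 largest increases and 5 largest decreases of each loading comparison that moved the same way in all 5 mice, the 5 largest of each sign for each age-by-loading difference, the 10 largest of each sign with age, and up to 4 members per described list with the smallest p. The first 3 parts needed an adjusted p under 0.05, a mean log2 CPM of at least 1 and a symbol that is no placeholder. Wnt1, Wnt7b, Sost, Col1a1, Bglap, Timp1 and Mki67 were named in each loading comparison. The few genes outside the rule are marked where they appear. Some genes that were called are not reported here by name.

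The size of the response was compared between ages by a score per mouse: the mean log2 difference between its tibias, signed by direction, over the genes called for the mean loading term of both ages on that day. The 5 and 5 mice were compared by an exact two-sided permutation test over 252 splits. In 1 set of data simulated with equal effects at both ages, the score over 179, 182 and 183 genes differed at 22 months by 0.00689 on day 1, 0.00732 on day 3 and -0.0343 on day 5 (exact permutation p = 0.667, 0.556 and 0.00794). In data simulated with 200 changed genes, the day 5 test at 5 months found 49.3%, 86.6% and 100% of genes changed 1.5-, 2- and 4-fold, and the age-by-loading test of day 5 found 11.9%, 67.2% and 87.9%.

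There were 13 alternatives fixed beforehand: DESeq2 size factors, library totals, no filter on low counts, DESeq2 1.42.0 as the test, no replicate block, a separate fit of the 10 libraries of an age and day, a 2-fold minimum, 3 tissue covariates (muscle, erythroid and other marrow lists), groups from the loading status field, only mice whose fields agree, leaving out each mouse, the estimated correlation, and a score over 500 genes. Another 3 were added after the data had been seen: a muscle covariate alone, a covariate of Gm42418, Lars2, Mir6236 and Gm15564 (the ribosomal repeat covariate, of which Lars2 and Gm15564 were not shown here to belong to the repeat), and the non-loaded fit without day 5. For 480 results on named genes and lists the test was repeated under the alternatives that apply. Splits of the samples were refitted for the 15 counts of genes, with the dispersion trend of the main fit held. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The RPKM and CPM columns of the files were not used here, and neither was the sequence of the reads.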

Results

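Both tibias of 30 female mice were measured, so every loading effect below is the difference between the loaded and the non-loaded tibia of the same 5 mice. Libraries held a median of 16.3 M counts (M, mega). Group medians ran from 12.72 M in loaded tibias of 5-month mice on day 5 to 18.93 M in non-loaded tibias of 22-month mice on day 3. Errors beside a log2 change are standard errors, and errors beside CPM values or per-mouse means are SD. Coordinates are of GRCm38.

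The loading status field of the labels contradicted the title for 30 of 60 libraries, in 14 mice for both tibias and in 2 mice for a single tibia. With groups from the titles, the 12 load-induced genes fixed from background were, on average, higher in the loaded tibia of 14 of 14 mice whose fields were exchanged (log2 0.313 to 2.016). The same genes were higher in 4 of 4 mice of days 3 and 5 whose fields agreed (0.606 to 1.317) and in 2 of 2 mice with a single contradictory field (0.619 to 1.442). All loading effects of days 3 and 5 are given with groups from the titles.

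Bone libraries carried RNA of neighbouring tissues in unequal amounts. Skeletal muscle transcripts made up as much as 21.41% of counts in a library, with means of 5.72 ± 3.26% at 5 months and 9.12 ± 4.46% at 22 months (n = 30 libraries each). In loaded and non-loaded tibias at 5 months they made up 6.91 ± 4.45% and 4.93 ± 3.21% on day 1, 6.48 ± 2.23% and 5.51 ± 2.38% on day 3, and 3.31 ± 1.42% and 7.2 ± 4.59% on day 5 (n = 5 each). At 22 months the shares were 5.64 ± 1.79% and 6.21 ± 3.58%, 8.04 ± 2.37% and 12.45 ± 4.14%, and 10.35 ± 4.51% and 12.06 ± 5.59% (n = 5 each). The muscle list was lower in the loaded tibia of 3 of 5 mice on day 5 at 5 months, with mouse 14 at 1.106. Gm42418, Lars2, Mir6236 and Gm15564, taken as markers of ribosomal RNA, made up 1.2 ± 0.77% of counts in 5-month mice of day 5 (n = 10 libraries of 5 mice), 0.13 ± 0.33% in other 5-month mice (n = 20 libraries of 10 mice) and 0.08 ± 0.03% at 22 months (n = 30 libraries of 15 mice). The non-loaded tibia of mouse 6 on day 3 held 1.51%, within the day 5 range of 0.24 to 2.76%, and without it the other 5-month libraries held 0.06 ± 0.05% (n = 19). Genes encoded by the mitochondrial genome took 3 ± 0.87% at 5 months and 1.75 ± 0.44% at 22 months (n = 30 libraries each).

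**Figure D1:**
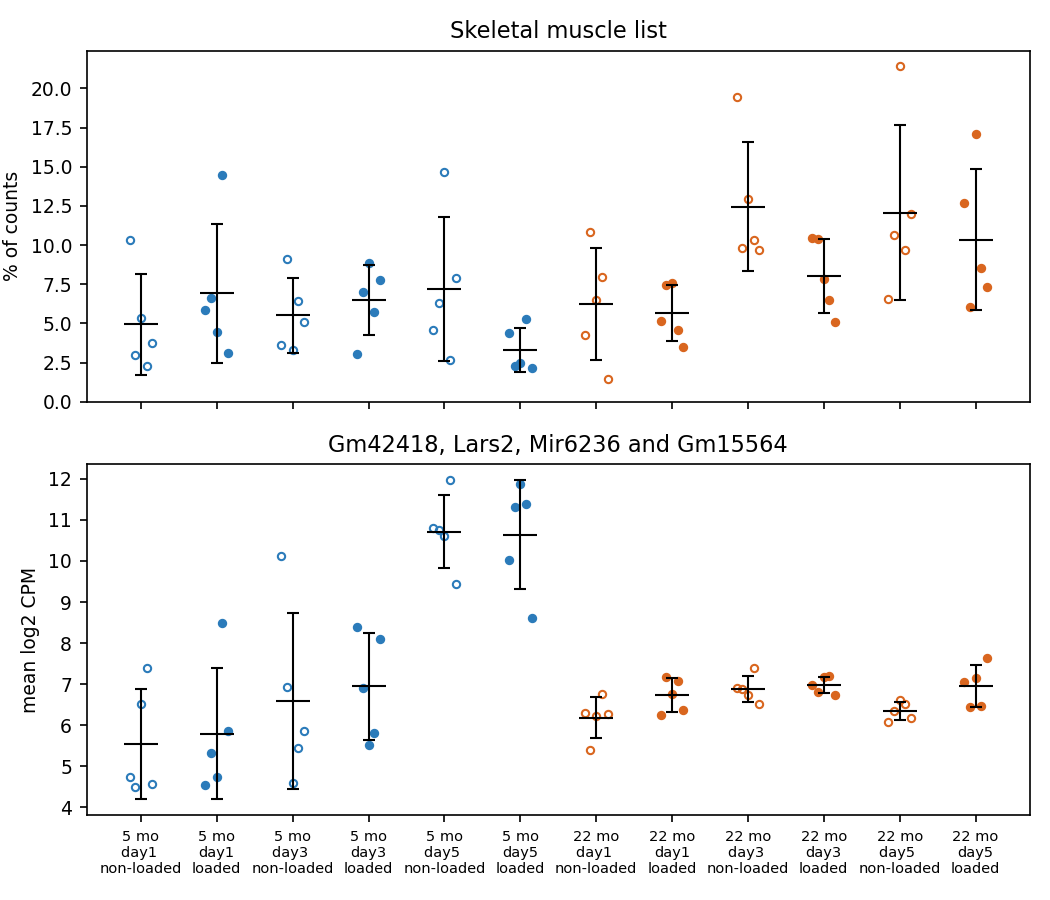
Share of counts in skeletal muscle genes (%) and mean log2 CPM of Gm42418, Lars2, Mir6236 and Gm15564 in each library, by age, day and loading (n = 5 per group). Muscle shares reach 21.41%, and these 4 genes are highest in 5-month mice of day 5, with the non-loaded tibia of mouse 6 on day 3 inside their range.

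After 1 day of loading at 5 months, 4 genes rose and none fell. Wnt1, a ligand of the Wnt pathway that drives bone formation (chromosome 15, 98789857 to 98793837), rose 5.58-fold, from 2.53 ± 1.02 to 14.7 ± 6.22 CPM (log2 2.48 ± 0.33, n = 5, adjusted p = 6.4e-04). Cxcl1, a chemokine that attracts neutrophils, rose 9.31-fold (3.22 ± 0.55, adjusted p = 0.0178), and Dusp6, a phosphatase induced by ERK signalling, rose 1.49-fold (0.57 ± 0.10, adjusted p = 0.0349). These were higher in the loaded tibia of 5 of 5 mice. Wnt7b, another Wnt ligand, was at 1.43 ± 0.33 (adjusted p = 0.258), Timp1, an inhibitor of matrix proteases, at 0.5 ± 0.32 (0.982), and Col1a1, the main collagen of bone, at 0.04 ± 0.28 (0.998). Sost, which encodes the Wnt inhibitor sclerostin, was at 0.01, the osteoblast product Bglap at 0.21 and the proliferation marker Mki67 at -0.3, none of them called.

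The 22 immediate early genes moved up as a list on day 1 at 5 months (median log2 0.47, camera adjusted p = 6.63e-13, and adjusted p = 0.045 with an estimated correlation). Of its members 1 passed over all genes and 7 did adjusted over the list alone. Fosb stood at 1.62 ± 0.40 (adjusted p = 0.406) and Egr1, a growth-induced transcription factor, at 0.84 ± 0.22 (0.453). The 23 inflammation genes were called upward with the preset correlation only (median 0.26, mean 0.72, camera adjusted p = 9.81e-07, adjusted p = 0.403 with an estimated correlation), with 1 member called over all genes and 6 adjusted over the list alone. Il6 was at 2.6 ± 0.65 (adjusted p = 0.406) and Ccl2, a monocyte chemokine, at 1.92 ± 0.57 (0.794). Early secreted response genes, 20 in number, had a median of 0.19 (camera adjusted p = 1.42e-04, adjusted p = 0.462 with an estimated correlation), 1 called over all genes and 4 adjusted over the list alone. Muscle genes had a median of 0.49, erythroid genes -0.30, B-cell precursor genes -0.25 and proliferation genes -0.22. Camera called these 4 lists, but with an estimated correlation it did not (adjusted p = 0.7 each), and none of their members was called.

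The day 1 count at 5 months was small and moved with single mice. It was 1 without mouse 1, 2 without mouse 2, 1 without mouse 3 and 9 without mouse 5. Wnt1 passed without any mouse, with a highest adjusted p of 0.0165. The call of Cxcl1 was lost without mouse 1 (log2 2.31, 0.289), 2 (3.31, 0.129) or 3 (3.19, 0.128), and that of Dusp6 without mouse 1 (0.63, 0.107), 2 (0.63, 0.0631), 3 (0.55, 0.387), 4 (0.48, 0.582) or 5 (0.57, 0.0876). Dusp6 did not pass scaled by library totals (0.48, 0.671). DESeq2 called 13 genes, among the added ones Cd44, Spred1, Pdgfa, Adamts9, Dot1l, Wnt7b, Wnt10b and Ddn, and a fit of these 10 libraries alone called 0 by edgeR, although 653 genes had an unadjusted p under 0.05 in the joint fit.

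After 3 days at 5 months, 351 genes rose and 187 fell. Of the members tested, 9 of 33 collagen and matrix genes and 8 of 27 osteoblast genes rose, and 8 of 20 osteoclast genes fell, while no list call held with an estimated correlation (adjusted p = 0.363, 0.431 and 0.383). Wnt1 rose 6.52-fold (log2 2.70 ± 0.32, n = 5, adjusted p = 9.2e-05). Serpina3n, a serine protease inhibitor, had the largest named increase at 13.26-fold (3.73 ± 0.54, adjusted p = 8.7e-04). Hapln4, a link protein of hyaluronan matrix, rose 5.49-fold (2.46 ± 0.39, 0.00129), the proteoglycan Bcan by 2.04 ± 0.39 (0.005) and Ddn by 2.62 ± 0.39 (9.3e-04). Col1a1 rose 2.07-fold, from 12200 ± 2180 to 25000 ± 3750 CPM (1.05 ± 0.28, adjusted p = 0.0379). Among the decreases, Pamr1 fell by 1.37 (log2 -1.37 ± 0.25, 0.00435). Every gene named here moved the same way in 5 of 5 mice.

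Rrad, a small GTPase, rose 7.81-fold on day 3 at 5 months (log2 2.97 ± 0.64, adjusted p = 0.0116), and lost its call without mouse 8 (2.89, 0.0633) or 10 (2.81, 0.0522). Card14, a scaffold of NF-kappaB signalling, rose by 2.57 ± 0.57 (0.014), and was at 2.42 without mouse 8 (0.0797) or mouse 10 (0.0592). The transcription factor St18 fell (-1.17 ± 0.24, 0.00849), with the call lost without mouse 8 (-1.1, 0.0526). Tnfrsf9 fell (-1.29 ± 0.27, 0.0104), with the call lost without mouse 8 (-1.16, 0.075) or 9 (-1.2, 0.0521), and so did Oscar, a receptor of osteoclasts (-1.18 ± 0.27, 0.015), with the call lost without mouse 6 (-1.13, 0.0616), 8 (-1.15, 0.0751) or 10 (-1.11, 0.0592). The metallothionein Mt2 rose by 1.74 ± 0.44 (0.0286), the transporter Slc10a6 by 1.66 (0.0237) and the sulfatase Arsi by 1.82 (0.0234). These 3 lost their calls without mouse 6, 8, 9 or 10, with a highest adjusted p of 0.111 for Mt2 (1.6 to 1.75 without these mice), 0.133 for Slc10a6 (1.48 to 1.8) and 0.106 for Arsi (1.66 to 1.88). Fgf23, the phosphate-regulating hormone of osteocytes, fell by 2.21 (log2 -2.21 ± 0.56, 0.0295), with the call lost without mouse 6 (-1.82, 0.139), 7 (-2.08, 0.08), 8 (-2.32, 0.0802) or 9 (-2.23, 0.0875). Timp1 rose 2.3-fold (1.2 ± 0.33, 0.0405), with the call lost without mouse 6 (1.04, 0.166), 8 (1.14, 0.162) or 9 (0.99, 0.175), and scaled by library totals (1.14, 0.0703). Col1a1 was not called without mouse 6 (1.03, 0.114), 7 (1.02, 0.0839), 8 (1.1, 0.104), 9 (0.92, 0.156) or 10 (1.13, 0.0666), nor by DESeq2 (1.04, 0.509), scaled by library totals (0.98, 0.0615) or in a fit of the 10 libraries alone (1.06, 0.0612). With 3 tissue covariates Arsi (1.32, 0.077), Mt2 (1.49, 0.0635), Fgf23 (-1.9, 0.0525) and Timp1 (1.1, 0.0751) lost their calls, and without the mouse block Mt2 (1.73, 0.0538), Slc10a6 (1.52, 0.0607), Tnfrsf9 (-1.3, 0.065) and Oscar (-1.17, 0.088) did. Wnt7b stood at 1.14 ± 0.33 (0.0558), Sost at -0.54 ± 0.28 (0.328), Bglap at -0.38 (0.586, lower in 3 of 5 mice) and Mki67 at -0.21 (0.714).

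Of 33 collagen and matrix genes, 9 rose and none fell on day 3 at 5 months (18 rose adjusted over the list alone, median log2 0.57, camera adjusted p = 7.66e-16, adjusted p = 0.363 with an estimated correlation). Fkbp10, a chaperone of collagen, rose by 1.08 ± 0.19 (0.0026), the prolyl hydroxylase P3h1 by 0.94 ± 0.18 (0.00456) and the crosslinking enzyme Lox by 1.07 ± 0.21 (0.00683). Of 27 osteoblast genes, 8 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.5, camera adjusted p = 5.91e-09, adjusted p = 0.431 with an estimated correlation). Creb3l1, a transcription factor that raises collagen output, rose by 1.43 ± 0.23 (0.00129), Smpd3 by 1.58 ± 0.27 (0.0026) and Tmem119 by 1.25 ± 0.21 (0.00256). Of 20 osteoclast genes none rose and 8 fell (17 fell adjusted over the list alone, median -0.61, camera adjusted p = 5.1e-13, adjusted p = 0.383 with an estimated correlation). The sodium-proton exchanger Slc9b2 fell by 1.07 (-1.07 ± 0.21, 0.00683), and Ctsk, the protease that degrades bone collagen, fell by 1.15 (-1.15 ± 0.25, 0.0112), with the call lost without mouse 8 (-1.07, 0.0734) or 10 (-0.99, 0.0592). Without the mouse block neither was called (Slc9b2 -1.09, 0.0634, and Ctsk -1.19, 0.069).

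On day 3 at 5 months, 4 of the 20 early secreted genes rose and 1 fell (10 and 1 adjusted over the list alone, median log2 0.9, camera adjusted p = 1.15e-05, adjusted p = 0.363 with an estimated correlation). Of 23 inflammation genes 4 rose and none fell, 9 adjusted over the list alone (median 0.3, mean 0.75, adjusted p = 0.556 with an estimated correlation). The monocyte chemokines Ccl7 and Ccl2 rose by 3.37 ± 0.57 (0.00248) and 2.46 ± 0.46 (0.00435). Of 23 Wnt feedback and inhibitor genes 3 rose (4 and 1 down adjusted over the list alone, median 0.14, adjusted p = 0.563 with an estimated correlation), with Apcdd1 at 1.43 ± 0.26 (0.00345) and Nkd2 at 0.94 ± 0.18 (0.00638). Of 19 osteocyte genes 1 fell, 4 adjusted over the list alone (median -0.26, adjusted p = 0.636 with an estimated correlation). Medians were -0.52 for B-cell precursor genes, -0.44 for erythroid genes and -0.39 for neutrophil genes (adjusted p = 0.477, 0.77 and 0.77 with an estimated correlation).

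The count of day 3 at 5 months was 157 without mouse 6, 114 without mouse 8, 183 without mouse 9 and 219 without mouse 10. Of the genes called, 65.2% rose. Scaled by library totals, which moved the median of all genes to -0.09, the share was 52.5% (168 up and 152 down).

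After 5 days at 5 months, 1757 genes rose and 1009 fell, among them 29 of 33 collagen and matrix genes and 22 of 27 osteoblast genes upward and 15 of 18 adipocyte genes downward (adjusted p = 0.0512, 0.0524 and 0.12 with an estimated correlation). Hapln4 rose 21.32-fold, from 0.651 ± 0.216 to 14.9 ± 5.27 CPM (log2 4.41 ± 0.42, n = 5, adjusted p = 4.2e-08). Car12, a carbonic anhydrase, rose 19.26-fold (4.27 ± 0.51, 9.4e-07) and Bcan 15.26-fold (3.93 ± 0.36, 3.8e-08). Col1a1 (chromosome 11, 94936224 to 94953042) rose 7.03-fold, from 13500 ± 3610 to 95300 ± 30900 CPM (2.81 ± 0.30, 1.8e-07). Bglap, which encodes osteocalcin, rose 5.76-fold, from 148 ± 63.8 to 796 ± 185 CPM (2.53 ± 0.33, 2.9e-06). Wnt1 rose 7.5-fold (2.91 ± 0.33, 3.6e-07) and Timp1 4.21-fold (2.07 ± 0.32, 3.8e-05). Each moved the same way in 5 of 5 mice, and all 18 genes named by rank or fixed beforehand that were called here passed without any single mouse.

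Other large increases on day 5 at 5 months were those of Cthrc1, a secreted protein of remodelling matrix, at 8.28-fold (log2 3.05 ± 0.35, adjusted p = 5.3e-07), Slc13a5, a citrate transporter (3.14 ± 0.32, 1.1e-07), the noradrenaline transporter Slc6a2 (3.11 ± 0.3, 5.5e-08), Creb3l3 (3.01 ± 0.4, 4.0e-06), Cgref1 (3.03, 4.7e-07) and Serpina3n (3.19 ± 0.55, 1.5e-04). The largest decreases were those of Cyp2e1, a cytochrome P450 (-2.96 ± 0.63, 0.00137), the striated muscle genes Perm1 (-2.91 ± 0.49, 1.0e-04), Smco1 (-2.83 ± 0.55, 5.4e-04) and Csrp3 (-2.82 ± 0.68, 0.00481), and Fgf23 (-2.73 ± 0.63, 0.00313). With 3 tissue covariates Cyp2e1 (-2.05, 0.0761), Csrp3 (-1.54, 0.104) and Fgf23 (-1.57, 0.246) were not called, and the loaded tibias held 3.31% muscle transcripts against 7.2%. Wnt7b was at 0.93 ± 0.33 (0.0548), Sost at -0.28 ± 0.28 (0.552, lower in 4 of 5 mice) and Mki67 at -0.39 ± 0.25 (0.311).

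**Figure D2:**
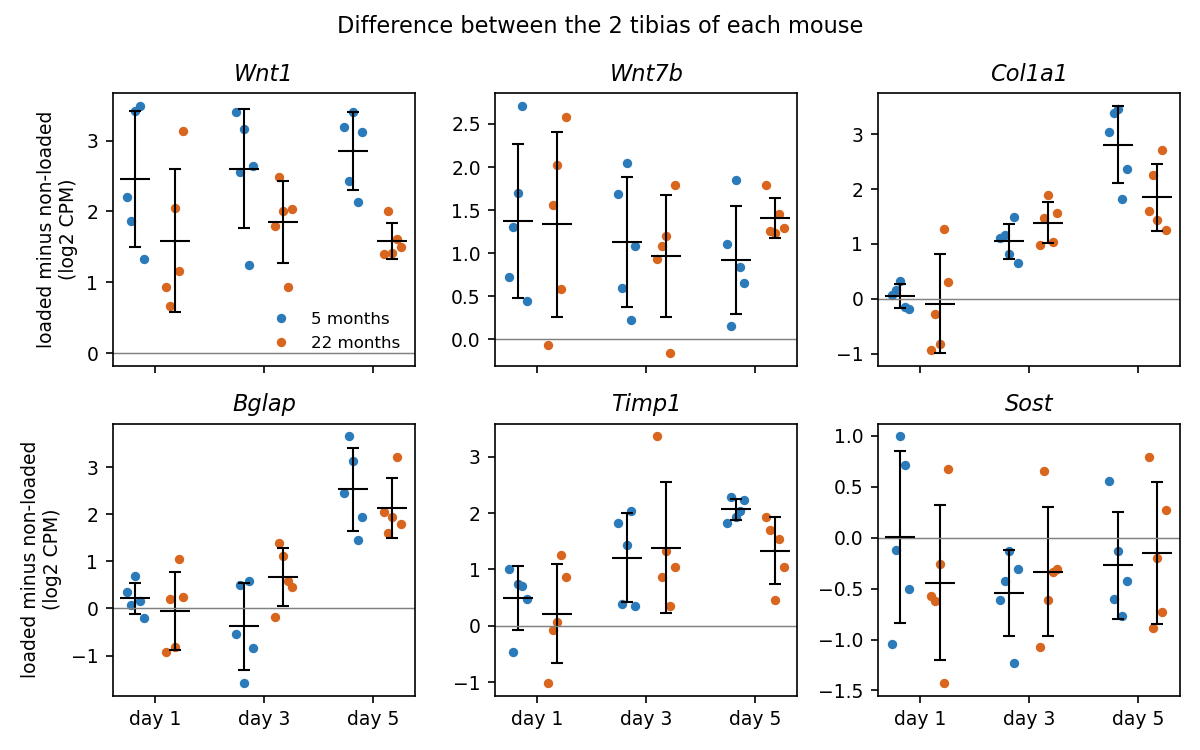
Log2 difference between the loaded and the non-loaded tibia of each mouse for Wnt1, Wnt7b, Col1a1, Bglap, Timp1 and Sost, by day and age (points are mice, lines are means, n = 5). Wnt1 is above 0 in all 30 mice, while at 5 months Col1a1 goes from 0.04 on day 1 to 2.81 on day 5.

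Of 33 collagen and matrix genes, 29 rose on day 5 at 5 months and none fell (30 adjusted over the list alone, median log2 1.32, camera adjusted p = 1.2e-33, adjusted p = 0.0512 with an estimated correlation). Lox rose 5.06-fold (2.34 ± 0.22, 3.8e-08), the fibrillar collagen Col5a2 by 2.33 ± 0.22 (4.2e-08) and P3h1 by 1.97 ± 0.18 (3.8e-08). Of 27 osteoblast genes 22 rose and none fell (24 adjusted over the list alone, median 1.63, camera adjusted p = 4.08e-28, adjusted p = 0.0524 with an estimated correlation), with Smpd3 at 2.81 ± 0.29 (1.1e-07). Early secreted genes had 12 members up and 1 down (16 and 1 adjusted over the list alone, median 0.93, adjusted p = 0.0543 with an estimated correlation). Of the 12 load-induced genes 6 rose, 9 adjusted over the list alone (median 1.3, adjusted p = 0.0524 with an estimated correlation). As the check of the labels, this list is no separate evidence of a response. Of 21 mechanosensing genes 8 rose (10 adjusted over the list alone, median 0.39, adjusted p = 0.353 with an estimated correlation), among them the gap junction gene Gja1 (1.63 ± 0.16, 8.7e-08) and the channels Trpv4 (1.07 ± 0.19, 2.6e-04) and Piezo1 (0.51 ± 0.09, 2.1e-04). Of 22 genes of secretion and the unfolded protein response 7 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.25, adjusted p = 0.546 with an estimated correlation). The transport coat gene Sec24d rose by 1.28 ± 0.13 (1.1e-07) and Ddit3, induced by severe stress of the endoplasmic reticulum, fell by 0.39 (-0.39 ± 0.08, 8.8e-04). Trpv4 (0.69, 0.0944), Piezo1 (0.34, 0.103) and Ddit3 (-0.28, 0.131) were not called with 3 tissue covariates.

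Of 18 adipocyte genes none rose and 15 fell on day 5 at 5 months (16 adjusted over the list alone, median log2 -1.17, camera adjusted p = 8.93e-10, adjusted p = 0.12 with an estimated correlation). Cidec, a lipid droplet protein, fell by 2.13 (-2.13 ± 0.42, 6.1e-04), the adipokine Cfd by 1.73 (-1.73 ± 0.36, 1.0e-03) and the lipase Lpl by 1.34 (-1.34 ± 0.3, 0.00235). Of 18 nerve and Schwann cell genes 1 rose and 8 fell, as many as adjusted over the list alone (median -0.47, adjusted p = 0.546 with an estimated correlation), with the neuronal tubulin Tubb3 up (2.37 ± 0.27, 5.3e-07) and the myelin gene Mbp down (-1.18 ± 0.18, 2.7e-05). Of 16 B-cell precursor genes 7 fell, 13 adjusted over the list alone (median -0.76, adjusted p = 0.386 with an estimated correlation). Pax5, the B-lineage transcription factor, fell by 0.76 (0.01), with the call lost without mouse 11 (-0.65, 0.061). Of 23 genes of oxidative phosphorylation 3 fell, 14 adjusted over the list alone (median -0.5, adjusted p = 0.546 with an estimated correlation). Of 23 inflammation genes 7 rose (8 adjusted over the list alone, median 0.27, mean 0.86, adjusted p = 0.546 with an estimated correlation), Il6 by 16.74-fold (4.07 ± 0.75, 3.0e-04). With 3 tissue covariates Cidec (-1.58, 0.0554), Cfd (-1.03, 0.191) and Pax5 (-0.42, 0.26) were not called, and without the mouse block Pax5 was not (-0.76, 0.103).

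Of 24 muscle genes 2 fell on day 5 at 5 months, 2 also adjusted over the list alone (median -0.89, adjusted p = 0.619 with an estimated correlation) and of 17 erythroid genes 1 (median -0.56, adjusted p = 0.612 with an estimated correlation). T and NK cell genes had a median of -0.41 with 3 down and neutrophil genes of -0.46 with none (adjusted p = 0.612 and 0.621 with an estimated correlation). Of 23 Wnt feedback and inhibitor genes 7 rose and 1 fell, as many as adjusted over the list alone, and their median of 0.14 turned to -0.07 when scaled by library totals (adjusted p = 0.546 with an estimated correlation). Camera called neither the 20 osteoclast genes (2 up, 1 down, median -0.28, adjusted p = 0.232), nor the 19 osteocyte genes (4 up, 1 down, median 0.17, 0.25), nor the 23 periosteal genes (6 up, 2 down, median 0.42, 0.193), nor the 14 senescence genes (1 up, median 0.06, 0.298). Adjusted over the list alone, osteocyte genes had 6 up and 1 down, periosteal genes 6 and 4, and the other pair the same counts. Wnt ligands, not called either (0.45), had a median of -0.05 but a mean of 0.03, with 4 up and 2 down, or 5 and 4 adjusted over the list alone.

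The count of day 5 at 5 months was 1830 without mouse 13, and 63.5% of the genes called rose. Scaling by library totals moved the median of all genes to -0.24 on day 5, and with it 879 genes rose and 4236 fell, a share up of 17.2%. With muscle transcripts as a covariate, an alternative chosen after seeing the data, 2331 rose and 2345 fell (49.9% up).

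After 1 day at 22 months edgeR called 0 genes (899 at an unadjusted p under 0.05), and Wnt1 and Dusp6 were again higher in the loaded tibia by value. Wnt1 was at 1.64 ± 0.33 and Dusp6 at 0.52 ± 0.10, each higher in 5 of 5 mice with an adjusted p of 0.166. DESeq2 called 4 genes, among them Wnt1, Dusp6 and the GTPase Gem, with adjusted p from 0.00313 to 0.00466. Without the mouse block edgeR called 33, and it called 2 without mouse 16 and 3 without mouse 19. Wnt7b was at 1.42 ± 0.34 (higher in 4 of 5 mice, adjusted p of 1), Sost at -0.44 and Col1a1 at -0.1.

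On day 1 at 22 months camera called the list of 20 endothelial genes upward with the preset correlation only (median log2 0.51, camera adjusted p = 8.13e-16, adjusted p = 0.24 with an estimated correlation). None of its members was called over all genes and 15 were adjusted over the list alone, with the VEGF receptor Kdr at 0.68 ± 0.19. The list mean per mouse was 0.448 ± 0.664 (n = 5), and mouse 17 was at 1.565, the next at 0.405. Of the immediate early genes none was called over all genes and 1 adjusted over the list alone (median 0.13, adjusted p = 0.831 with an estimated correlation). The T and NK cell genes had a median of -0.31 and the ribosomal protein genes of -0.16, called by camera but not with an estimated correlation (adjusted p = 0.831 each).

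After 3 days at 22 months, 526 genes rose and 75 fell, with 21 of 33 collagen and matrix genes and 16 of 27 osteoblast genes among the increases (adjusted p = 0.0374 and 0.055 with an estimated correlation). Wnt1 rose 3.75-fold (log2 1.91 ± 0.32, n = 5, adjusted p = 6.7e-04). Cthrc1 rose 4.36-fold (2.13 ± 0.34, 5.7e-04), Tubb3 by 2.06 ± 0.26 (1.5e-04), the chaperone Fkbp11 by 1.87 ± 0.3 (4.7e-04), Smpd3 by 1.75 ± 0.27 (4.7e-04), Slc13a5 by 1.72 ± 0.3 (0.0011), Hapln4 by 1.99 ± 0.37 (0.00196) and Bcan by 1.87 (0.00299). Col1a1 rose 2.62-fold, from 14000 ± 5020 to 35800 ± 10200 CPM (1.39 ± 0.28, 0.0039), though it was not called by DESeq2 (1.38, 0.394). Dusp10, a phosphatase of stress kinases, fell by 0.85 (-0.85 ± 0.16, 0.00185). These genes moved the same way in 5 of 5 mice and passed without any single mouse.

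Some calls of day 3 at 22 months were lost with 4 mice in place of 5, while the sign of the log2 change stayed the same. Timp1 rose by 1.34 ± 0.33 (adjusted p = 0.0176), with the call lost without mouse 21 (0.9, 0.158) or 23 (1.35, 0.0767). Serpina3n rose by 2.04 ± 0.53 (0.0277), with the call lost without mouse 21 (1.48, 0.205), 23 (1.84, 0.165) or 24 (2.05, 0.0907). Ddn rose by 1.73 (0.00694), a call lost without mouse 23 (1.61, 0.0589) or 25 (1.52, 0.0505). The ketone enzyme Bdh1 fell (-1.06 ± 0.26, 0.0164), a call lost without mouse 21 (-0.85, 0.148) or 23 (-0.98, 0.0987). Nr4a1, an immediate early receptor gene, fell as well (-1.0 ± 0.25, 0.0214), as did Pamr1 (-0.87, 0.0464) and Depp1 (-0.79, 0.0315). These 3 were not called without mouse 21, 23, 24 or 25, with a highest adjusted p of 0.115, 0.234 and 0.178 and log2 changes of -0.92 to -1.01, -0.7 to -1.02 and -0.65 to -0.84. Timp1 (1.16, 0.143), Serpina3n (1.51, 0.177), Bdh1 (-0.71, 0.18), Pamr1 (-0.9, 0.115) and Depp1 (-0.6, 0.212) were not called with 3 tissue covariates, nor were Timp1 (1.34, 0.106), Serpina3n (2.06, 0.095) and Depp1 (-0.79, 0.0527) in a fit of the 10 libraries alone. Without the mouse block Bdh1 (-0.93, 0.0929), Nr4a1 (-1.0, 0.159), Pamr1 (-0.85, 0.307) and Depp1 (-0.76, 0.254) were not. The count was 349 without mouse 21, 231 without mouse 23 and 385 without mouse 24. With 3 tissue covariates it was 214 (196 up and 18 down), against 601 without them. Wnt7b was at 1.07 (0.0883, higher in 4 of 5 mice), Bglap at 0.68 (0.301), Sost at -0.34 (0.637) and Mki67 at -0.12, none of them called.

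Of 33 collagen and matrix genes 21 rose and none fell on day 3 at 22 months (29 adjusted over the list alone, median log2 0.77, camera adjusted p = 1.89e-34, and adjusted p = 0.0374 with an estimated correlation). Col5a1 rose by 1.29 ± 0.18 (2.7e-04) and the collagen chaperone Serpinh1 by 1.47 ± 0.22 (4.5e-04). Of 27 osteoblast genes 16 rose, 23 adjusted over the list alone (median 0.94, camera adjusted p = 1.11e-24, adjusted p = 0.055 with an estimated correlation), with Tmem119 at 1.49 (2.8e-04). The 12 load-induced genes had 5 members up, 8 adjusted over the list alone (median 1.11, camera adjusted p = 6.11e-11, and adjusted p = 0.0374 with an estimated correlation). As the check of the labels, this list is no separate evidence of a response. Of 23 inflammation genes 4 rose, 5 adjusted over the list alone (median 0.38, adjusted p = 0.441 with an estimated correlation), among them Ccl2 at 2.07 (0.00477), not called with 3 tissue covariates (1.83, 0.078). Il11, a cytokine of bone and early secreted gene, rose by 2.81 ± 0.52 (0.0019). Of 22 secretion and unfolded protein response genes 4 rose, 8 adjusted over the list alone (median 0.3, adjusted p = 0.339 with an estimated correlation). Adipocyte genes had a median of -0.53 with 1 member down (adjusted p = 0.286 with an estimated correlation). With none called, oxidative phosphorylation genes had a median of -0.42, muscle genes of -0.78 and osteoclast genes of -0.29 (adjusted p = 0.459, 0.674 and 0.718 with an estimated correlation).

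After 5 days at 22 months, 642 genes rose and 188 fell. Upward went 27 of 33 collagen and matrix genes and 19 of 27 osteoblast genes (adjusted p = 0.0201 and 0.0353 with an estimated correlation), and downward 9 of 16 B-cell precursor, 2 of 22 T and NK cell and 1 of 16 plasma cell genes (adjusted p = 0.195, 0.262 and 0.418 with an estimated correlation). Bcan rose 6.39-fold (log2 2.68 ± 0.39, n = 5, adjusted p = 1.7e-04) and Cthrc1 by 2.59 ± 0.36 (9.8e-05). Bglap rose 4.33-fold, from 102 ± 16.5 to 458 ± 169 CPM (2.11 ± 0.32, 2.2e-04). Col1a1 rose 3.61-fold, from 10700 ± 1210 to 40200 ± 14200 CPM (1.85 ± 0.29, 2.8e-04), and Wnt1 3.07-fold (1.62 ± 0.32, 0.00216). The protease Prss35 rose by 2.21 ± 0.3 (8.5e-05), Slc13a5 by 2.12 (1.4e-04), Hapln4 by 2.08 ± 0.4 (0.00196), the collagen Col11a1 by 2.06 ± 0.26 (2.9e-05) and the growth factor Ptn by 2.03 ± 0.34 (5.4e-04). The immunoglobulin segment Ighj2 fell by 2.04 (-2.04 ± 0.4, 0.0024) and Tnfrsf13c, the BAFF receptor of B cells, by 1.19 (-1.19 ± 0.2, 4.6e-04). These moved the same way in 5 of 5 mice and passed without any single mouse. A fit of these 10 libraries alone, which called 28 genes in all, did not call Bcan (2.68, 0.0531), Cthrc1 (2.59, 0.0531), Ptn (2.04, 0.0628), Hapln4 (2.08, 0.101), Tnfrsf13c (-1.19, 0.121), Col1a1 (1.86, 0.122) or Ighj2 (-2.03, 0.166), and DESeq2 did not call Col1a1 (1.84, 0.176).

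Wnt7b rose 2.8-fold on day 5 at 22 months (log2 1.49 ± 0.35, adjusted p = 0.0111), a call lost without mouse 26 (1.37, 0.0689) or 27 (1.52, 0.0502). Timp1 rose by 1.36 ± 0.32 (0.0116), a call lost without mouse 26 (1.2, 0.0877), 27 (1.27, 0.0888) or 29 (1.31, 0.0505). Col3a1 rose by 2.19 ± 0.51 (0.00955), a call lost without mouse 26 (1.84, 0.0852) or 27 (1.7, 0.0995), and Car12 by 2.11 ± 0.47 (0.00642), lost without mouse 27 (1.88, 0.0683). Fgf23 fell (-1.79 ± 0.48, 0.0274), a call lost without mouse 26 (-1.48, 0.179), 27 (-1.57, 0.171), 28 (-1.79, 0.0636) or 29 (-1.84, 0.0672). The immunoglobulin segments Igkj5 (-1.32, 0.0389) and Iglv3 (-1.25, 0.0173) fell as well. The call of Igkj5 was lost without mouse 26 (-0.89, 0.294), 27 (-1.19, 0.22) or 28 (-1.4, 0.0632) and that of Iglv3 without mouse 26 (-0.73, 0.179) or 27 (-1.24, 0.0974). Wnt7b (1.25, 0.0724), Timp1 (1.2, 0.123), Col3a1 (1.23, 0.183), Fgf23 (-1.09, 0.324), Igkj5 (-0.95, 0.132) and Iglv3 (-0.66, 0.254) were not called with 3 tissue covariates. The fit of the 10 libraries alone called none of Timp1, Col3a1, Car12, Fgf23, Igkj5 and Iglv3, with log2 changes within 0.01 of those above. Sost was at -0.16 (0.838) and Mki67 at -0.37 (0.492). The count was 362 without mouse 26, 268 without mouse 27 and 551 without mouse 29.

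Of 33 collagen and matrix genes 27 rose and none fell on day 5 at 22 months (31 adjusted over the list alone, median log2 1.12, camera adjusted p = 1.12e-40, and adjusted p = 0.0201 with an estimated correlation), with Col5a1 at 1.53 (2.9e-05) and the crosslinking enzyme Loxl2 at 1.72. Of 27 osteoblast genes 19 rose and none fell (24 adjusted over the list alone, median 1.18, camera adjusted p = 7.73e-30, and adjusted p = 0.0353 with an estimated correlation), with Smpd3 at 1.84 and Creb3l1 at 1.56. The 12 load-induced genes had 7 members up, 8 adjusted over the list alone (median 1.43, adjusted p = 0.0352 with an estimated correlation). As the check of the labels, this list is no separate evidence of a response. Of 16 B-cell precursor genes 9 fell, 11 adjusted over the list alone (median -0.88, camera adjusted p = 6.48e-08, adjusted p = 0.195 with an estimated correlation). Cd22, a receptor of B cells, fell by 0.87 (-0.87 ± 0.19, 0.00458), with the call lost without mouse 26 (-0.75, 0.0531) or 27 (-0.76, 0.0647) and without the mouse block (-0.91, 0.104). Of 16 plasma cell genes 1 fell, 6 adjusted over the list alone (median -0.83, adjusted p = 0.418 with an estimated correlation). Other marrow lists stood lower too, with medians of -0.63 for erythroid, -0.49 for T and NK cell and -0.37 for neutrophil genes (adjusted p = 0.516, 0.262 and 0.645 with an estimated correlation). Erythroid transcripts made up 0.3% of counts in loaded and 0.62% in non-loaded tibias, so a lower content of marrow is not set apart from a response of B cells. Mouse 26 had an erythroid difference of -2.571, the other mice -0.454 to 0.24. Wnt ligands had 3 members up and 5 adjusted over the list alone, Wnt feedback and inhibitor genes 4 and 5 (medians 0.46 and 0.32, adjusted p = 0.195 each with an estimated correlation). Mechanosensing genes had 3 up, 6 adjusted over the list alone (median 0.33, adjusted p = 0.195 with an estimated correlation), with Gja1 at 1.11 (1.7e-04). None of the adipocyte genes was called (median -0.23, adjusted p = 0.645 with an estimated correlation). Secretion and unfolded protein response genes had a median of 0.08, which turned to -0.02 when scaled by library totals (2 up, adjusted p = 0.678 with an estimated correlation).

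Of the genes called on day 5 at 22 months 77.3% rose. The share was 65.5% when scaled by library totals (363 up, 191 down, median of all genes -0.12) and 52.6% with a muscle covariate (996 up, 897 down).

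**Figure D3:**
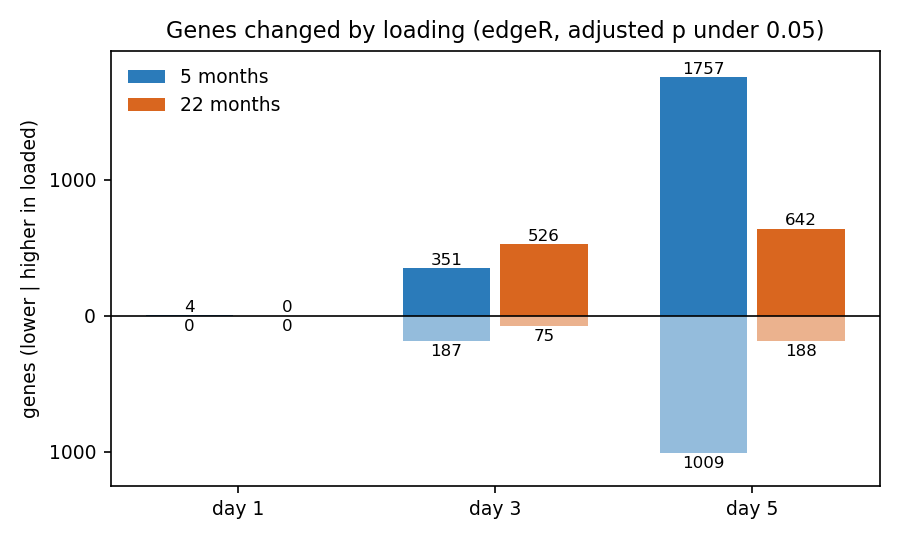
Number of genes higher and lower in the loaded tibia (edgeR, adjusted p under 0.05) by day and age, each from 5 mice. Counts go from 4 to 538 to 2766 at 5 months and from 0 to 601 to 830 at 22 months.

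**Figure D4:**
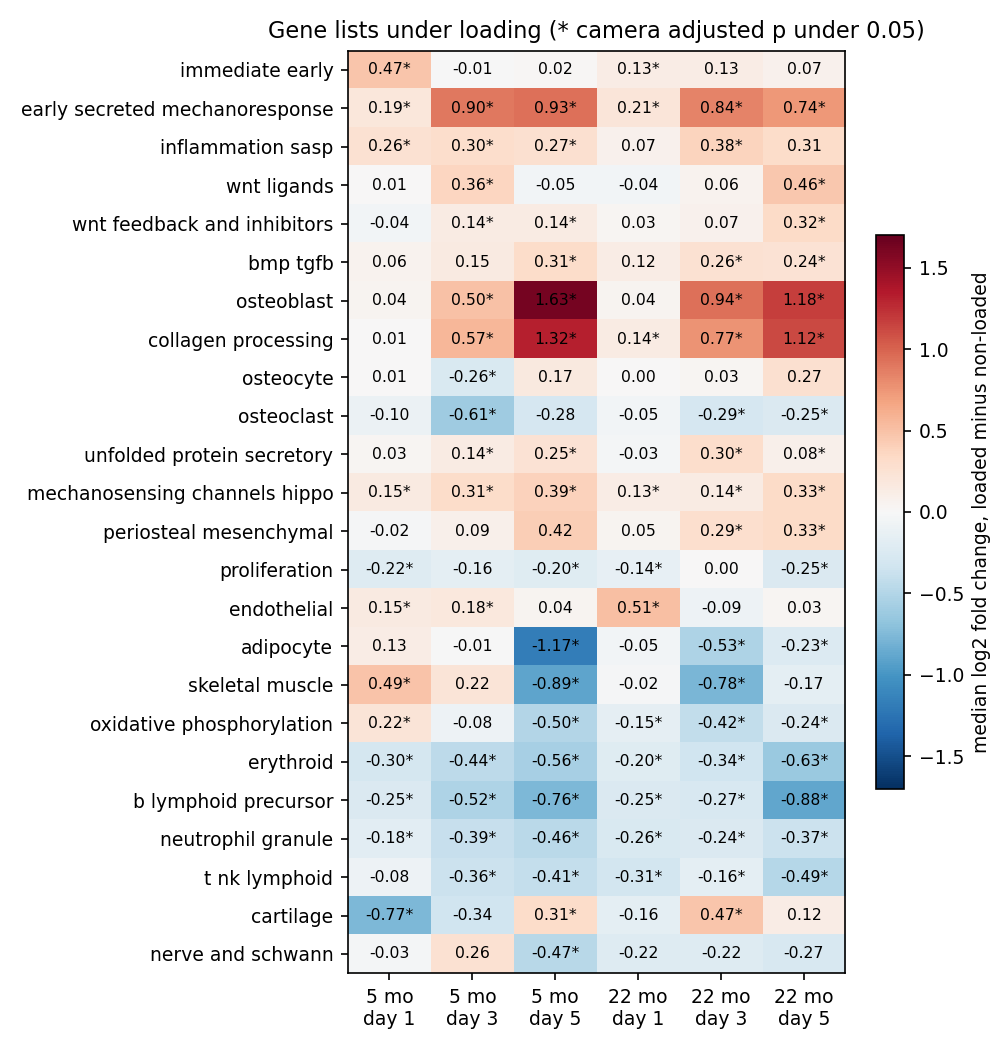
Median log2 difference between loaded and non-loaded tibias for 24 gene lists (rows) in 6 combinations of age and day (columns). Stars mark a camera adjusted p under 0.05 with the preset correlation, and collagen and osteoblast lists are called on days 3 and 5 at both ages.

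The response at 5 months changed with the days of loading. The difference between days, tested with 2 degrees of freedom, was called for 526 genes. The log2 change of Col1a1 was 0.04, 1.05 and 2.81 on days 1, 3 and 5 (adjusted p = 4.4e-04), and P3h1 at -0.05, 0.94 and 1.97 (1.4e-04). Bglap was at 0.21, -0.38 and 2.53 (6.1e-04). The proline enzyme Pycr1 (-0.24, 0.88, 2.19) and the collagen Col11a2 (0.03, 0.65, 2.54) had the smallest adjusted p (5.2e-05 each), and Hapln4 went from -0.08 to 2.46 and 4.41 (2.4e-04). These last 3, like P3h1, were chosen here after their values were seen, and no list was tested between days. With 3 tissue covariates the count was 92. Wnt1 stood at 2.48, 2.70 and 2.91 (0.92). The count was 313 without mouse 12 and 286 without mouse 13.

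At 22 months the difference between days was called for 14 genes. Chosen after their values were seen were Col5a1 (0.19, 1.29, 1.53), Cthrc1 (0.02, 2.13, 2.59), Tubb3 (0.09, 2.06, 1.52), Fkbp11 (-0.33, 1.87, 1.37) and Pycr1 (-0.01, 1.15, 1.39), each with an adjusted p of 0.0473. The count was 0 by edgeR without mouse 16, 17, 18, 21, 23, 25, 27 or 29, while 1158 genes had an unadjusted p under 0.05 with all mice and DESeq2 called 119. It was 6 without mouse 26, 28 without mouse 20, 37 without mouse 28, 49 without mouse 30 and 145 without mouse 19. Days 3 and 5 shared 305 increases and 80 decreases at 5 months, where 33.3 and 10.2 would be shared if the calls were independent. At 22 months they shared 373 increases and 14 decreases (18.2 and 0.8).

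The ages shared much of the response. On day 3, 194 genes rose at both ages and 14 fell at both (10 and 0.8 under independence), and on day 5, 593 rose and 96 fell at both (60.8 and 10.2). No gene was called in opposite directions. Of the genes called at 5 months on day 5, 1711 of 1757 increases and 966 of 1009 decreases had the same sign at 22 months. On day 3 it was 348 of 351 and 174 of 187.

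The difference of the loading effect between ages was tested directly, and edgeR called 0 genes on each day and over the mean of days. At an unadjusted p under 0.05 there were 389, 805 and 845 genes on days 1, 3 and 5, and 680 for the mean. DESeq2 called 0, 0, 1 and 0. Col1a1 was 0.96 lower in its day 5 effect at 22 months (log2 -0.96 ± 0.40, adjusted p of 1), Hapln4 stood at -2.33 (0.72) and Wnt1 at -1.29 ± 0.45 (0.973). The gene DESeq2 called was Adamts8, a protease of the matrix, singled out after its values were seen. Its difference was 2.66 ± 0.56 by DESeq2 (0.0432) and 2.7 ± 0.59 by edgeR (0.457).

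Lists differed between ages by camera with the preset correlation only, which called 42 of 96 over the 3 days. All with a median beyond 0.3 are given here with some others. On day 5 the 18 adipocyte genes had a median difference of log2 0.76 (22 minus 5 months, camera adjusted p = 2.82e-12, adjusted p = 0.249 with an estimated correlation). No adipocyte gene was called over all genes and 5 were adjusted over the list alone. On the same day the muscle list differed by 0.71, the Wnt ligands by 0.54, the mitochondrial genome by 0.5, the nerve list by 0.41, the interferon list by 0.31, the osteoblast list by -0.52, the plasma cell list by -0.38 and the collagen list by -0.26 (adjusted p = 0.67 each with an estimated correlation). On day 3 the muscle list differed by -0.97, the osteoclast list by 0.53, the adipocyte list by -0.53, the load-induced list by 0.47, the mitochondrial genome by -0.43, oxidative phosphorylation by -0.36, the Wnt ligands by -0.32, the endothelial list by -0.32, the collagen list by 0.32 and the osteoblast list by 0.31 (adjusted p = 0.592 each with an estimated correlation). The cartilage list differed by 0.67, the nerve list by -0.42 and the macrophage list by 0.31 that day (adjusted p = 0.73 each with an estimated correlation). On day 1 the mitochondrial genome differed by -0.54, oxidative phosphorylation, inflammation and immediate early lists by -0.43, -0.33 and -0.26 and the endothelial list by 0.32 (adjusted p = 0.721 each with an estimated correlation), and the muscle list by -0.51 (adjusted p = 0.948 with an estimated correlation). Over the mean of days ribosomal protein genes had a median difference of -0.05, which turned to 0.04 when scaled by library totals (adjusted p = 0.993 with an estimated correlation).

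The size of the response per mouse was compared by an exact two-sided permutation test of 5 against 5 mice, and no day passed with all mice. On day 5 the mean signed change over 4342 genes was 0.631 ± 0.095 at 5 months and 0.444 ± 0.19 at 22 months, a difference of -0.187 (exact permutation p = 0.111). On day 3 it was 0.5 ± 0.072 and 0.498 ± 0.131 over 1739 genes (difference -0.002, exact permutation p = 0.984), and on day 1 it was 1.299 ± 0.5 and 0.922 ± 0.591 over 11 genes (-0.378, exact permutation p = 0.294). Without mouse 5 the day 1 difference was -0.607 (exact permutation p = 0.04) and without mouse 16 it was 0.004. The day 5 difference was -0.274 without mouse 14 (exact permutation p = 0.032), -0.132 without mouse 28 (exact permutation p = 0.206) and -0.088 without mouse 30 (exact permutation p = 0.405). The day 3 difference changed sign without mouse 6, 8, 9, 22, 24 or 25, within -0.067 to 0.091. In data simulated with equal effects at both ages the day 5 score differed by -0.0343 (exact permutation p = 0.00794), so a bias of the score on that day is not excluded.

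**Figure D5:**
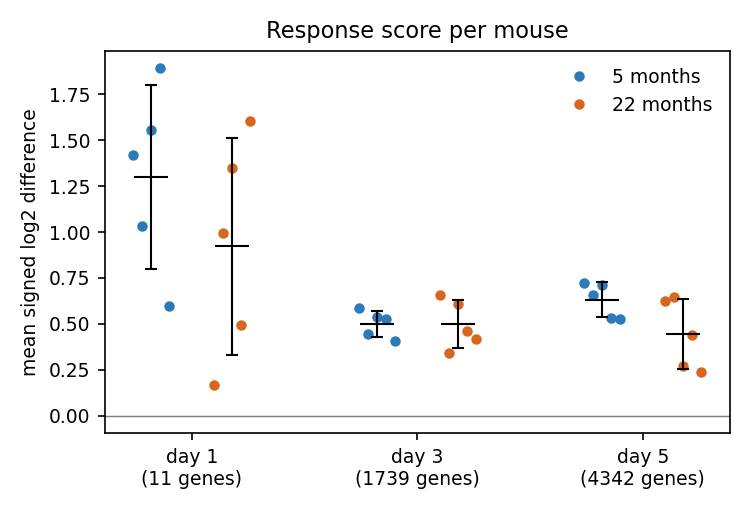
Mean signed log2 change per mouse over the genes called for loading at both ages together (11, 1739 and 4342 genes on days 1, 3 and 5), by day and age (points are mice, lines are means, n = 5). Day 5 means are 0.631 at 5 months and 0.444 at 22 months, and the mice of both ages overlap.

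In non-loaded tibias, 3846 genes were higher and 3581 lower at 22 than at 5 months (n = 15 each, 17967 genes tested). With 3 tissue covariates 3290 were called, 2645 of them shared with these 7427. Lower with age were 12 of 17 cartilage, 30 of 38 proliferation and 14 of 17 erythroid genes, and higher were 10 of 16 plasma cell, 16 of 22 T and NK cell and 21 of 23 oxidative phosphorylation genes. Camera called these lists, but none with an estimated correlation (adjusted p = 0.552 to 0.59). Acan, the main proteoglycan of cartilage, was lower by 3.17 (log2 -3.17 ± 0.47, adjusted p = 8.6e-06), its link protein Hapln1 by 3.61 (-3.61 ± 0.5, 3.4e-06) and the cartilage collagens Col9a2 (-3.53 ± 0.61, 5.3e-05), Col9a1 (-3.12 ± 0.68, 7.3e-04) and Col9a3 (-2.92) likewise. Elovl4, an elongase of fatty acids, was lower as well (-3.38 ± 0.21, 1.7e-12). Ccl8, a monocyte chemokine, was higher (3.19 ± 0.28, 1.9e-09), as were the B-cell receptor gene Fcrl5 (3.3 ± 0.32), the immunoglobulin genes Igkv4-55 (2.78 ± 0.55, 2.8e-04) and Ighv1-55 (2.78), and Tnnc2, a troponin of fast muscle (3.43 ± 0.34, 1.6e-08). Small RNAs and ribosomal genes also ranked high: Rnu3a (4.21 ± 0.17, 1.7e-16), Rpl38 (3.18), mt-Ta (2.76) and Snord17 (2.7). All 20 genes ranked by size passed without any single mouse. With 3 tissue covariates Col9a2 (-2.73, 0.051), Ighv1-55 (2.65, 0.0539), Col9a1 (-3.28, 0.0844) and Col9a3 (-2.25, 0.11) were not called.

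Tbx4, a transcription factor of the hindlimb (-3.68 ± 0.29, adjusted p = 2.0e-10), Foxe3 (-3.57), Pou3f1 (-3.37), Fam124a (-2.92) and Cadps2 (3.04 ± 0.26, 1.7e-09) also changed with age. Their size depended on day 5, where the 5-month libraries stood apart. Without day 5, an alternative chosen after seeing the data, the values were -2.2, -1.97, -2.06, -1.74 and 3.95, all still called. Cartilage genes stood lower still without day 5: Acan at -4.07, Hapln1 at -4.56, Col9a2 at -4.5, Col9a1 at -3.83 and Col9a3 at -3.77. The difference of the cartilage list between tibias varied at 5 months. Its SD was 2.704, 2.301 and 0.408 on days 1, 3 and 5 (n = 5 mice each), against 0.472, 0.542 and 0.704 at 22 months. None of the 3 tissue covariates held the cartilage list.

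Of 17 cartilage genes 12 were lower with age and none higher (1 higher and 12 lower adjusted over the list alone, median log2 -2.92, adjusted p = 0.559 with an estimated correlation). The value after each further median is likewise the adjusted p with an estimated correlation, with which camera kept no call on age. Of 38 proliferation genes 30 were lower, 32 adjusted over the list alone (median -0.58, 0.59), such as Ube2c (-1.01) and Ccna2 (-0.75, but -0.21 and not called with 3 tissue covariates). Of 17 erythroid genes 14 were lower, 14 also adjusted over the list alone (median -0.77, 0.559), such as Hba-a2 (-2.12). Of 26 genes of BMP and TGF-beta signalling 15 were lower, 16 adjusted over the list alone (median -0.35, 0.552), such as Tgfb1 (-0.89 ± 0.09, 1.1e-08). Of 33 collagen genes 12 were lower and 1 higher, 13 and 1 adjusted over the list alone (median -0.18, 0.672), Col3a1 by -2.14 ± 0.25 (3.0e-07). Of the 12 load-induced genes 8 were lower and 1 higher, the same adjusted over the list alone (median -0.85, 0.552). Periosteal genes had 9 lower and 2 higher of 23, also adjusted over the list alone (median -0.25, 0.672), with Postn at -0.84.

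Of 23 oxidative phosphorylation genes 21 were higher with age, 23 adjusted over the list alone (median log2 0.6, adjusted p = 0.552 with an estimated correlation), such as Cox5b (1.16, 5.4e-07). The value after each further median is again the adjusted p with an estimated correlation. By contrast 6 of 7 tested protein genes of the mitochondrial genome were lower, 7 adjusted over the list alone (median -1.67, 0.552), such as mt-Nd6 (-2.26, 2.8e-10). Outside that list, the RNA genes mt-Ta (edgeR adjusted p = 9.2e-09) and mt-Rnr1 (0.96, 0.00199) of the same genome were higher. Of 22 T and NK cell genes 16 were higher, 17 adjusted over the list alone (median 0.6, 0.552), such as the granzyme Gzmk (3.69 ± 0.35, 8.0e-09). Plasma cell genes had 10 of 16 higher, 10 also adjusted over the list alone (median 0.7, 0.552), with Mzb1 at 1.79 ± 0.23 (9.2e-07). Of 22 secretion and unfolded protein response genes 15 were higher (median 0.28, 0.552), of 18 adipocyte genes 12 (median 0.56, 0.552), of 24 muscle genes 11 (median 0.77, 0.672) and of 21 glycolysis genes 12 higher and 1 lower (median 0.38, 0.559). Adjusted over the list alone these counts were 17, 13, 13, and 13 with 1 lower. Inflammation genes had 10 higher and 1 lower of 20 (median 0.49, 0.552), osteoclast genes 8 and 2 of 20 (median 0.3, 0.672) and ribosomal protein genes 10 and 5 of 28 (median 0.2, 0.744). Adjusted over the list alone they had 10 and 1, 11 and 2, and 11 and 5.

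Camera called neither the 27 osteoblast genes with age (4 higher, 7 lower, median 0.04, mean -0.04, adjusted p = 0.684) nor the 19 osteocyte genes (2 higher, 5 lower, median -0.17, 0.0706), though Sost was lower at 22 months (log2 -0.7 ± 0.19, 0.00529). Col1a1 was at -0.08 (0.643). The 14 senescence genes had 3 higher and 5 lower (median -0.25, mean -0.09, 0.268). Adjusted over the list alone, osteoblast genes had 4 higher and 7 lower, osteocyte genes 3 and 7, and senescence genes 3 and 6. Among the last, Cdkn2a, an inhibitor of the cell cycle singled out after its values were seen, was higher at 22 months (1.52 ± 0.20, 1.5e-06). No batch of libraries is given in the labels, and any batch that followed age would be the same as age in this comparison.

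Non-loaded tibias differed between days within an age. At 5 months 438 genes did, 280 of them highest on day 1, 34 on day 3 and 124 on day 5. This count was 171 with the ribosomal repeat covariate (149 shared with the 438), 1121 with 3 tissue covariates and 146 without day 5. The genes named here were chosen after their values were seen, and no list was tested for this comparison. Fkbp5, a co-chaperone of the glucocorticoid receptor, was at 8.09 ± 0.2, 6.51 ± 0.33 and 6.07 ± 0.28 log2 CPM on days 1, 3 and 5 (n = 5 each, adjusted p = 2.8e-06), Mt2 at 7.99, 5.81 and 4.96 (4.9e-08) and Ddit4, an inhibitor of mTOR signalling, at 8.15, 6.04 and 4.87 (1.2e-06). The matricellular gene Ccn1 was at 8.13, 6.2 and 5.74 (1.8e-06). At 22 months 29 genes differed between days, 25 of them highest on day 1. Fkbp5 (0.267), Mt2 (0.193) and Ddit4 (0.0861) were not among them, and the difference between ages was not tested here.

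The count of genes that differed between days in non-loaded tibias at 22 months moved with single mice. It was 5 without mouse 16, 12 without mouse 17, 55 without mouse 18, 166 without mouse 19, 6 without mouse 20, 16 without mouse 21, 60 without mouse 22, 17 without mouse 28, 9 without mouse 29 and 19 without mouse 30. Each loading effect above was taken against the tibia of the same mouse and day.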

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

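Chosen only after the result was seen were the test of the loading status field, the spread among responding genes, the use of the response score (a score fixed beforehand) as a test of the day 5 counts, the day 5 effect at 22 months, and the splits for day 5 at 5 months, for age, for the age difference of day 5 and of the mean, and for days at 5 months.

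Among 90 sets of 5 values checked, 2 held a mouse far from the other 4, where chance gives about 1 in 20 such groups (4.5 of 90). On day 5 at 22 months the Bglap difference of mouse 29 was 3.22, against 1.61 to 2.04 in the others, and the Mki67 difference of mouse 26 was -1.98, against -0.16 to 0.17. Mouse 26 also had the lowest erythroid (-2.571), neutrophil (-1.827) and B-cell precursor (-1.356) differences of its group, and its erythroid share was 1.53% in the non-loaded and 0.25% in the loaded tibia. No explanation was tested for either mouse.

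Of 96 list differences between ages, 5 had an exact two-sided permutation p under 0.05 (5 against 5 mice), where chance gives 4.8, and none did after adjustment (lowest 0.858). On day 3 the osteoclast list differed by 0.473 (-0.674 ± 0.274 at 5 and -0.201 ± 0.164 at 22 months, exact permutation p = 0.024). The adipocyte list on day 3 differed by -0.599 (-0.022 ± 0.447 and -0.621 ± 0.293, exact permutation p = 0.048). Glycolysis genes on day 3 differed by -0.306 (0.028 ± 0.157 and -0.278 ± 0.217, exact permutation p = 0.048), and Wnt ligands by -0.346 (0.409 ± 0.16 and 0.063 ± 0.195, exact permutation p = 0.024). On day 5 the adipocyte list differed by 0.938, from -1.178 ± 0.397 at 5 months to -0.239 ± 0.689 at 22 months (exact permutation p = 0.032).

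The loading effect differed between days for 526 genes at 5 months and 14 at 22 months. At 5 months 1 of 100 splits of the mice gave as many genes, the real one, and the highest other gave 70. At 22 months 3 of 100 gave as many, with 21 as the highest other, above the real 14. The share at 5 months is the smallest that 100 splits can give. Neither share is adjusted over the 15 counts split, so chance is not excluded by them. The 22-month count was 0 without mouse 16, 17, 18, 21, 23, 25, 27 or 29 by edgeR, where 1158 genes had an unadjusted p under 0.05 with all mice and DESeq2 called 119. It was 6 without mouse 26, 28 without mouse 20, 37 without mouse 28, 49 without mouse 30 and 145 without mouse 19.

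The pattern of contradictory labels was weighed first. If the loading status field were right, the load-induced list would be higher in the title's non-loaded tibia, but it was higher in the title-loaded tibia in 14 of 14 exchanged mice. This argues against the field and leaves open how it came to differ. No biological explanation was tested.

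The second pattern is that 2766 genes were called on day 5 at 5 months and 830 at 22 months, a ratio of 3.33 (separate fits called 1464 and 28, and the 22-month count ran from 268 without mouse 27 to 1104 without mouse 30), while no gene differed between ages by edgeR (845 at an unadjusted p under 0.05, 1 by DESeq2). Muscle and marrow on the bone as the whole cause is argued against, since the ratio was 3.24 with 3 tissue covariates (1116 and 344 genes). The 2766 and 830 genes came from 1 fit in which all mice share 1 estimate of the spread. A larger spread between mice at 22 months would there widen the errors of both ages. What it would do to these counts was not tested, so a larger spread stays open for them and for the separate fits. The ratio of the spreads was 0.99 over all genes (0.75 to 1.19 leaving out 1 mouse). It was 1.05 over responding genes (0.87 to 1.24). A smaller response at 22 months also stays open, with a score difference of -0.187 (exact permutation p = 0.111), which was -0.274 without mouse 14 (exact permutation p = 0.032), -0.132 without mouse 28 (exact permutation p = 0.206) and -0.088 without mouse 30 (exact permutation p = 0.405). In data simulated with equal effects at both ages the day 5 score also differed, by -0.0343 (exact permutation p = 0.00794). Whether the real score carries a bias on day 5 was not settled. Age, as the design names it, may contribute, and it was not told apart from the spread.

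The third pattern is a set of 46 genes over 1 log2 unit higher in non-loaded tibias of 5-month mice on day 5 than on both other days, such as Tbx4, Foxe3 and Pou3f1, with a median of 2.21 over day 3, of which 40 differed with age. The day 5 libraries that chose the set are also part of the age comparison, which called 7427 of 17967 genes. The 40 are therefore no separate evidence of a change with age. GC content is argued against, since other genes of like GC moved by 0.04 (SD 0.28), and so is a day effect shared by both ages, since the set moved by -0.04 at 22 months (-0.77 to 0.39). Residual ribosomal RNA stays open, as the set holds Gm42418 and Mir6236 of the ribosomal repeat. It also holds Gm15564 (4.33 over day 3) and Lars2 (4.06), taken above as markers, and the mitochondrial ribosomal RNA mt-Rnr1 (1.97). With Gm42418 and Mir6236 left out, 0 of 44 members held a 20-base stretch of the transcripts searched (upper 95% limit 8.04%), but the share among other genes was 0.129%, too low for 44 genes to show an excess, and the rest of the repeat was not searched. A batch of libraries that holds the 5-month mice of day 5 is confounded with the group and stays open, as does a biological difference of these mice.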

How the results depend on the processing

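The muscle covariate, the ribosomal repeat covariate and the fit without day 5 were chosen after seeing the data. None of 304 called gene results reversed under the alternatives listed next, and groups from the loading status field, not run gene by gene, turned the direction of the day 5 counts. Calls lost numbered 94 with 3 tissue covariates, 23 with library totals, 14 with no low-count filter, 2 with DESeq2 size factors, 3 of 303 with the DESeq2 test, 42 of 219 with no replicate block, 77 of 217 in the separate fit, 9 with the muscle covariate, 15 with the ribosomal repeat covariate, 2 of 85 without day 5 and 95 without some mouse. With only mice whose fields agree, 2 per group on day 3, all 88 were lost. Unless said otherwise the cause was not tested. For day 1 at 5 months the DESeq2 test called 13 genes and the separate fit 0, and for day 1 at 22 months the DESeq2 test called 4 and the fit with no replicate block 33. For day 3 at 5 months counts were 114 at 2-fold, 320 with library totals, 314 with no filter, 919 with the DESeq2 test, 347 with no replicate block, 1099 with the muscle covariate, and 0 by edgeR both with groups from the field and with only agreeing mice (3245 at an unadjusted p under 0.05 in full). For day 5 at 5 months they were 694 at 2-fold, 5115 with library totals, 1464 in the separate fit, 1116 with 3 covariates and 4676 with the muscle covariate, and groups from the field gave 1925 with the direction reversed. For day 3 at 22 months they were 132 at 2-fold, 214 with 3 covariates, and 0 by edgeR with the field or with only agreeing mice (2748 at an unadjusted p under 0.05 in full). For day 5 at 22 months they were 217 at 2-fold, 28 in the separate fit, 344 with 3 covariates and 1893 with the muscle covariate, and the field gave 5 with the direction reversed. The age difference of day 5 had 1 gene with the DESeq2 test, 2 with 3 covariates and 1 with the muscle covariate. Age in non-loaded tibias had 710 at 2-fold and 3290 with 3 covariates. Days of loading at 5 months had 839 with the DESeq2 test and 92 with 3 covariates. At 22 months they had 4 with DESeq2 size factors, 24 with no filter, 119 with the DESeq2 test, 2 with no replicate block and 43 with the muscle covariate, and 0 by edgeR with library totals or the ribosomal repeat covariate (1158 at an unadjusted p under 0.05 in full). Non-loaded tibias between days had at 5 months 751 with the DESeq2 test, 1121 with 3 covariates, 731 with the muscle covariate, 171 with the ribosomal repeat covariate and 146 without day 5. At 22 months they had 11 with library totals, 10 with no filter, 214 with the DESeq2 test, 6 with the muscle covariate, and 0 by edgeR with 3 covariates or without day 5 (2309 at an unadjusted p under 0.05 in full). The day 3 response score difference turned to 0.07 over 500 genes, 0.03 with library totals and 0.016 with no filter.

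Of 176 list calls, 170 were lost with an estimated correlation, 65 with 3 covariates, 42 with the muscle covariate, 22 with library totals, 10 of 158 with no replicate block, 9 with no filter, 6 with the ribosomal repeat covariate and 5 with DESeq2 size factors. With 3 covariates 16 reversed, several on the lists the covariates hold. Neutrophil genes turned up at 5 months on days 1, 3 and 5 (camera adjusted p of 0.283, 0.163 and 0.0622) and at 22 months on days 3 and 5 (0.627 and 0.00708). Proliferation genes turned up on day 5 at 5 months (0.000676) and at 22 months on days 1 (0.718) and 5 (5.28e-07). Erythroid genes reversed on day 3 at 5 months (0.935), on day 1 at 22 months (0.718) and with age (0.434), plasma cell genes on day 1 at 5 months (0.997), and muscle genes on day 3 at 22 months (0.883) and with age (0.0796). Oxidative phosphorylation (0.513) and interferon genes (0.92) reversed in the age difference of day 3. With the muscle covariate 5 reversed: neutrophil genes on day 1 at 5 months (0.914), muscle genes on day 3 at 22 months (0.705) and with age (0.0831), and interferon (0.772) and macrophage genes (0.768) in the age difference of day 3.

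Leaving out each mouse in turn gave, on days 1, 3 and 5, counts of 1 to 9, 114 to 431 and 1830 to 2755 at 5 months and of 0 to 3, 231 to 685 and 268 to 1104 at 22 months. It gave 0 to 0 for each age difference of loading by edgeR (389, 805, 845 and 680 at an unadjusted p under 0.05), 6969 to 7796 for age, 286 to 699 and 0 to 145 for days of loading at 5 and 22 months, and 303 to 476 and 5 to 166 for non-loaded tibias between days. The response score difference ran from -0.623 to 0.004 on day 1, from -0.067 to 0.091 on day 3 and from -0.274 to -0.088 on day 5. Depth limits genes near the filter, which kept 18543 of 41388.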

Other observations

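Chosen only after the result was seen were the splits for day 5 at 5 months, for age, and for the age difference of day 5 and of the mean.

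Each loading count was compared with other exchanges of the tibias within the 5 mice. There are 16 such splits, too few for a share under 0.05. Day 1 at 5 months had 4 genes against a highest other of 9 (2 of 16 as large), day 3 538 against 1 (1 of 16) and day 5 2766 against 874 (1 of 16). At 22 months day 1 had 0 genes by edgeR (899 at an unadjusted p under 0.05, 4 by DESeq2) against 172 (16 of 16 as large), day 3 601 against 1 (1 of 16) and day 5 830 against 21 (1 of 16). What made a split of day 1 at 22 months call 172 genes was not tested. Splits that did not part every pair, 84 in each comparison, can keep part of the contrast of loading. Their highest counts on days 1, 3 and 5 were 27, 56 and 2046 at 5 months (1, 0 and 0 as large as the real count) and 808, 435 and 1437 at 22 months (84, 0 and 7 as large).

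For age in non-loaded tibias 1 of 100 splits gave as many genes as the real 7427, and the highest other gave 1244, so chance is excluded at this share. For days in non-loaded tibias at 5 months it was 1 of 100 (438 against 26). At 22 months it was 6 of 100 (29 against 1030), so chance is not excluded. What made a split call 1030 genes was not tested. The age differences of loading had 0 genes by edgeR with 389, 805, 845 and 680 at an unadjusted p under 0.05 on days 1, 3, 5 and over the mean (0, 0, 1 and 0 by DESeq2). For them 100 of 100 splits on each day and 25 of 25 for the mean were as large, with highest others of 272, 1, 2 and 0.

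Tibias of the same mouse were somewhat more alike than tibias of different mice of a group. The correlation across genes of centred values had a median of 0.15 (-0.33 to 0.59, 30 pairs) within a mouse and -0.05 (-0.56 to 0.44, 120 pairs) between mice, where genes are not independent replicates. Sln, a regulator of the calcium pump of muscle singled out after its values were seen, differed in its day 5 effect between ages with 3 tissue covariates (-3.93 ± 0.62, adjusted p = 0.0173) and with the muscle covariate (-3.78 ± 0.6, 0.0166), against -2.98 ± 0.92 (0.908) with neither. The transcript Gm14236 took 3.0 ± 1.02% of counts at 5 months and 0.78 ± 0.28% at 22 months (n = 30 libraries each).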
